A study of Mus musculus with 4 samples.

How the data were processed

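The study profiled leukocytes from the left ventricle of C57Bl6J mice after sham treatment or DOCA-salt, a deoxycorticosterone acetate and salt regimen that raises blood pressure. The mice's hearts were perfused, minced and digested, and cells carrying CD45 were enriched and stained with hashtag antibodies, which mark the mouse of origin, and with antibodies to surface proteins. The cells of 4 mice per group were pooled, sorted and loaded for 5' single-cell sequencing, so all sham mice are in 1 library and all DOCA-salt mice in the other. Library and group therefore cannot be told apart by any test of these data. No paired analysis was possible because the hashtag numbers mark mice within a library and link no sham mouse to a DOCA-salt mouse.

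The deposited matrices hold raw UMI counts (unique molecules) per feature and barcode, for 31053 genes and 20 antibody features, of which 4 are hashtags and 16 are surface antibodies. The authors produced these counts with Cell Ranger, for which the matrix headers give software version 3.1.0, and the submitters' processing notes also name Seurat 4 and the mm10 build. The deposited feature and barcode lists are of other kinds (text identifiers), with no measured values. The sham library holds 4359 barcodes and the DOCA-salt library 7600, with 13304511 and 29764964 RNA UMIs.

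Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which left 4254 sham and 7351 DOCA-salt cells. Scrublet, run per library through scanpy 1.11.5, called 97 sham cells (2.28%) and 243 DOCA-salt cells (3.31%) doublets, and these were removed. A cell was assigned to a mouse when its highest hashtag count was at least 2 times the second, and 136 sham cells (3.20%) and 321 DOCA-salt cells (4.37%) failed this. Scrublet called 19.1% of those sham cells and 24.0% of those DOCA-salt cells, against 1.72% and 2.36% of assigned cells. The analysis used 4047 sham and 6864 DOCA-salt cells, with a median of 2807 and 3228 UMIs. Single mice contributed 621 to 1268 sham cells and 764 to 2172 DOCA-salt cells, with 1764007 to 4004282 UMIs per sham mouse and 2708758 to 9048096 per DOCA-salt mouse.

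Counts were normalised per cell, log transformed, reduced to 2000 variable genes and 30 principal components, and clustered with 15 neighbours by the Leiden method (leidenalg 0.10.2) at resolution 1.0 on both libraries together, without batch correction. A cluster was called "X-like" from cell type markers fixed before the data were examined. A marker counted when at least 15% of the cluster's cells held it and it was raised by a log2 fold of 1.0, and 3 were needed. The rules that left a cluster with markers of several lineages unnamed were set after the clusters were seen. There were 23 clusters, of which 6 stayed unnamed.

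For each class and mouse, UMIs were summed over cells. Genes were filtered with filterByExpr, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with the mouse as the replicate, 4 against 4. Values are log2 changes of DOCA-salt against sham, with p adjusted by the Benjamini-Hochberg method within each class and a threshold of 0.05. Shares of classes were compared by a two-sided exact permutation test, whose smallest p is 0.0286 with 4 mice against 4, and adjusted over the 14 classes and unnamed clusters tested. Gene lists fixed beforehand were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, using members with at least 20 CPM (a gene's UMIs scaled to a common total for the class and mouse) and at least 3 measured members. DESeq2 1.42.0 was an alternative test. The depth of the tests differs by class. UMIs per mouse ran from 114450 to 1895998 in macrophage-like cells, 9169 to 372187 in classical monocyte-like cells and 896538 to 3019878 in B-like cells. Intervals on shares of cells are 95% Clopper-Pearson intervals and cover counting error only.

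The genes named in the text follow a rule fixed before the data were examined. Trem2 and Tyrobp are always named. In macrophage-like and classical monocyte-like cells up to 12 genes per direction are named, and in the other classes up to 5, by largest change among genes past the threshold with a mean of at least 50 CPM and no overlap between the groups' mice. Numbered gene models, ribosomal protein, mitochondrial, haemoglobin, sex-linked and antigen receptor genes were left out of that ranking. Of each list given, up to 4 measured members with the largest change are named. Genes that lead a cluster are named to describe it. Other genes named were chosen after their values were seen. Positions come from GENCODE release M21 (GRCm38, equal to mm10), matched by gene identifier.

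The edgeR test was tested on simulated data with the depth of each class, in which 200 genes per class were changed. Of genes changed 2-fold it recovered from 57.6% in classical monocyte-like cells to 86.5% in NK-like cells, of genes changed 4-fold at least 97.9%, and 2.89% to 7.65% of its calls were of unchanged genes. Every class of the real data had fewer calls than 200. These rates depend on how many genes change, so they need not hold for the real tests. Alternatives fixed beforehand covered the cell filter, doublets, clustering, the hashtag margin, scaling, weighting of cells and clusters, thinning to 1000 UMIs of each cell that holds at least that many, expression floors, the test, and leaving out each mouse. Alternatives added after the data were seen are named as such where they are given. Neutrophil-like and cDC2-like cells, with 13 and 26 sham cells, were not tested for gene expression.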

Results

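The series asks how leukocytes of the heart differ in hypertensive heart disease, and its title names Trem2, a lipid-sensing receptor of macrophages that signals through the adaptor Tyrobp. Each class below compares 4 DOCA-salt mice with 4 sham mice. Because each group was sequenced as 1 library, every difference given here is also a difference between libraries.

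B-like cells made up less of the leukocytes of DOCA-salt hearts, and classical monocyte-like cells made up more. B-like cells averaged 59.2% ± 4.03 of cells in sham mice and 46.6% ± 3.66 in DOCA-salt mice (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.1), with 4 of 4 DOCA-salt mice below all sham mice. Classical monocyte-like cells averaged 0.374% ± 0.169 and 1.63% ± 0.566 (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.1), with 4 of 4 DOCA-salt mice above all sham mice. No share passed the threshold after adjustment over the 14 shares tested. The smallest exact permutation p is 0.0286, so a share could pass only if most of the 14 reached it together. The monocyte difference depended on the joint clustering. With each library clustered on its own it was 0.0573 percentage points, against 1.25.

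Neutrophil-like cells averaged 0.323% ± 0.269 in sham mice and 2.65% ± 1.65 in DOCA-salt mice (SD, n = 4; exact permutation p = 0.0571, adjusted p = 0.16). The shares of NK-like cells (12.3% and 17.1%), T-like cells (9.28% and 12.03%), macrophage-like cells (7.63% and 10.3%), nonclassical monocyte-like cells (2.17% and 1.55%) and cDC2-like cells (0.608% and 1.43%) differed by less than the exact permutation test could separate. Much of the macrophage-like and cDC2-like differences rests on DOCA-salt mouse 1. Without it they fell from 2.65 to 0.847 and from 0.826 to 0.260 percentage points, and with each library clustered on its own the macrophage-like one was 0.614. Over the alternatives that kept all mice the cDC2-like difference ran from 0.688 to 1.45. Without DOCA-salt mouse 4 the NK-like difference fell from 4.80 to 2.23, and without DOCA-salt mouse 3 the T-like one fell from 2.76 to 1.58. Without B-like cells in the denominator the NK-like difference was 1.95 and the macrophage-like one 0.749. The nonclassical monocyte-like difference of -0.611 was -0.371 without sham mouse 1, -0.369 without DOCA-salt mouse 1 and -2.51 without B-like cells in the denominator. With each library clustered on its own it was -2.84, because no DOCA-salt cluster was named nonclassical monocyte-like. Of the unnamed clusters, one led by B cell genes, with macrophage markers raised as well, averaged 4.35% and 1.95%, with 4 of 4 DOCA-salt mice below all sham mice. Another, led by Cd163l1 and gamma-delta T cell receptor genes, averaged 0.423% and 1.68%, with 4 of 4 DOCA-salt mice above. Both had an exact permutation p of 0.0286 and an adjusted p of 0.1.

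**Figure D1:**
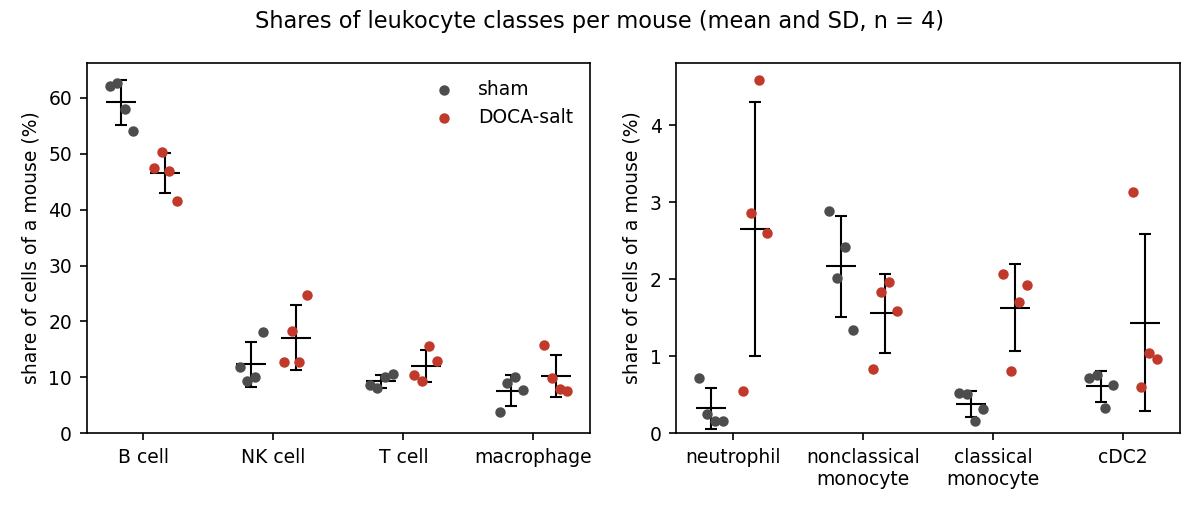
Share of a mouse's cells (%) in each of 8 classes, with 1 point per mouse and bars for the mean and SD (n = 4 per group). B-like cells average 59.2% in sham and 46.6% in DOCA-salt mice, and the 2 groups' points do not overlap.

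Within B-like cells, 1 cluster was led by the lambda light chain genes Iglv1 and Iglc1, with Vpreb3, Ly6d and Cd24a. Vpreb3 and Cd24a are genes of less mature B cells, while Ly6d also led the largest B-like cluster, so maturity is not settled. This cluster led by Iglv1 averaged 13.2% ± 1.35 of the class in sham mice and 2.31% ± 1.79 in DOCA-salt mice (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0857). A cluster led by Fcrl5, Mzb1 and Zbtb32 averaged 1.49% ± 0.562 and 3.90% ± 1.38, with the same p values. Within T-like cells, a cluster led by Igfbp4, Lef1 and Cd4 averaged 49.9% ± 4.13 and 36.3% ± 2.83, again with the same p values by the exact permutation test. None of these passed after adjustment, which with this test needed most of a class's clusters to reach the smallest p together. Macrophage-like cells formed 3 clusters, led by C1q genes (57.1% and 64.0% of the class), by Fabp5 and Cbr2 with Spp1 (17.8% and 17.4%) and by Mrc1 and Stab1 (25.1% and 18.5%), and the exact permutation test separated the groups in none (p = 0.114, 0.943 and 0.2). The cluster led by Mrc1 had a median of 1186 UMIs and 5.35% mitochondrial UMIs per cell, against 4526 and 1.92% in the one led by C1q genes. Cell quality may therefore set it apart as well as cell state. Without DOCA-salt mouse 1 the difference in the cluster led by Mrc1 went from -6.60 to -2.48 percentage points. Spp1 in the cluster led by Fabp5 came from DOCA-salt mouse 1, with 564 UMIs there, whereas 1 of the 53 sham cells held any. That mouse had 34.0% of its macrophage-like cells in the cluster, and the other DOCA-salt mice had 8.86% to 17.03%.

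Trem2 was detected in macrophage-like and monocyte-like cells. In macrophage-like cells it was higher in DOCA-salt mice without passing the threshold over all genes. It averaged 201 CPM ± 27.0 in sham mice and 332 CPM ± 92.1 in DOCA-salt mice, with a log2 change of 0.71 (SE 0.21; adjusted p = 0.239 by edgeR) and 4 of 4 DOCA-salt mice above all sham mice. A Trem2 UMI was found in 32.2% of sham macrophage-like cells (98 of 304; 95% interval 27.0% to 37.8%) and 55.7% of DOCA-salt ones (413 of 742; 52.0% to 59.3%). Their median depths were 2905.5 and 3814.5 UMIs, so the share of cells rises with depth as well as with expression. In B-like cells, which should lack the gene, the share was 0.459% and 1.82% at median depths of 2622 and 2902 UMIs. In classical monocyte-like cells, at median depths of 8885 and 9300 UMIs, it was 31.3% (5 of 16) and 47.8% (54 of 113). Trem2 averaged 45.7 CPM ± 47.2 and 88.2 CPM ± 23.1 in them (SD, n = 4; exact permutation p = 0.171). Sham mouse 3 had 1 cell of this class, and its 109 CPM is 1 UMI. In nonclassical monocyte-like cells the share with a Trem2 UMI was 4.76% (4 of 84) and 14% (14 of 100) at median depths of 3848 and 4693 UMIs. Trem2 averaged 27.5 CPM ± 36.6 and 32.3 CPM ± 18.4 there (SD, n = 4; exact permutation p = 0.8286). Tyrobp, the adaptor, averaged 2573 and 2454 CPM, with a log2 change of -0.09 (adjusted p = 0.916). Its log2 change was 0.04 in classical monocyte-like, 0.11 in nonclassical monocyte-like, -0.17 in B-like, -0.10 in NK-like and -0.47 in T-like cells (adjusted p = 0.083 in the last). Trem2 lies on chromosome 17 from 48346401 to 48354147 on the forward strand, and Tyrobp on chromosome 7 from 30413760 to 30417585.

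In macrophage-like cells, S100a4, a calcium-binding protein of motile cells, and Ms4a4a, a membrane protein of macrophages, rose in DOCA-salt mice. Mmp13, a collagenase, and Cyr61, a matrix-associated signalling protein, fell, as did Per1 and Tsc22d3, which respond to corticosteroids. Gatm, Gpr65, Tgfbr1 and Malat1 also fell. In all, 11 of 4624 genes passed the threshold, 2 higher and 9 lower, and 404 had an unadjusted p under 0.05.

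S100a4 averaged 103 and 316 CPM (log2 change 1.54, SE 0.28, adjusted p = 0.0332), and Ms4a4a 114 and 381 CPM (log2 change 1.53, adjusted p = 0.0417). Cyr61 had the smallest adjusted p, 0.0019, with 89.4 and 21.5 CPM (log2 change -2.30). Mmp13 averaged 285 and 54.7 CPM (log2 change -2.39). Per1 changed by -1.65, Gatm by -1.23, Tsc22d3 by -1.19, Gpr65 by -0.94, Tgfbr1 by -0.93 and Malat1 by -0.78 on the log2 scale. With clusters weighted equally Cyr61 changed by -1.07, Per1 by -1.03 and Tgfbr1 by -0.61, and none of the 3 passed. Of the alternatives that measured each gene, the call was lost in 15 of 26 for Tgfbr1, 14 of 25 for Mmp13, 13 of 27 for Malat1, which also reversed in 1 more, 11 of 25 for Gpr65, 10 of 27 for Tsc22d3, 9 of 26 for S100a4, 9 of 25 for Ms4a4a, 7 of 23 for Per1, 3 of 25 for Gatm and 2 of 22 for Cyr61. Every one of the 11 genes had no overlap between the groups' mice, against 5.84% of all genes tested and 2.86% by chance. The 11 were called on these same values, so the lack of overlap is not separate support. The calls rest on few counts in some mice. Within the C1q-led cluster alone, an alternative added after the data were seen, edgeR called 0 genes, with 338 at an unadjusted p under 0.05, and DESeq2 was not run there. On the whole class DESeq2 called 20.

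**Figure D2:**
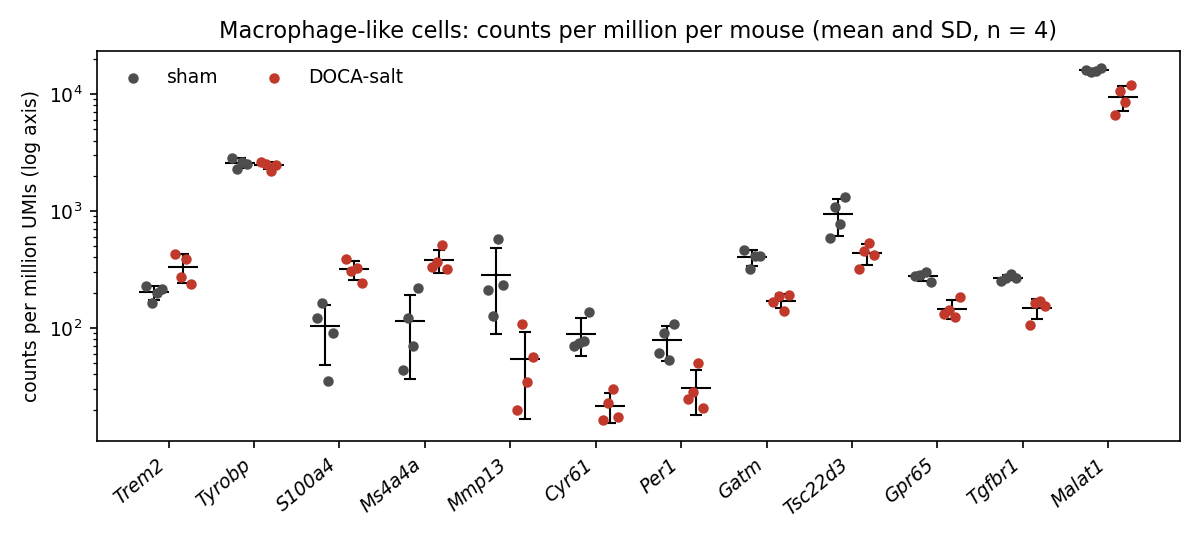
CPM (log axis) in macrophage-like cells for Trem2, Tyrobp and the 10 named genes past the threshold, with 1 point per mouse and bars for the mean and SD (n = 4 per group). Trem2 averages 201 in sham and 332 in DOCA-salt mice, and Cyr61 averages 89.4 and 21.5.

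Among the 15 measured members of a list of TREM2 and lipid-associated genes, 0 passed by edgeR over all genes, while 5 higher and 3 lower passed adjusted over the list alone. The largest changes were Ctsd (1.07), Cd36 (-0.78), Cd9 (-0.77) and Ctsl (0.76) on the log2 scale. The members moved both ways, with a median of 0.13, and the list did not pass (adjusted p = 0.329 by camera). Apoe, named after its values were seen, averaged 10477 and 17077 CPM.

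Spp1, a matrix protein of macrophages in injured tissue that was named after its values were seen, came almost wholly from 1 mouse. DOCA-salt mouse 1 held 1963 Spp1 UMIs in 160 of 341 macrophage-like cells (46.9%), whereas the other DOCA-salt mice held 21, 3 and 14 UMIs and the sham mice 0, 7, 2 and 5.

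Nonclassical monocyte-like cells of DOCA-salt mice had more Chil3, a chitinase-like protein of inflammatory monocytes, and more Tgfbi, an adhesion protein of the matrix. Hp, S100a6 and Ms4a4a rose with them. Ddit4, L1cam, Ly6i, Fam46a and Aldh3b1 fell. In all, 37 of 1514 genes passed the threshold, 11 higher and 26 lower.

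Chil3 averaged 16.9 CPM in sham and 412 CPM in DOCA-salt mice (log2 change 4.88, SE 0.50, adjusted p = 3.9e-07). Tgfbi changed by 1.93, Hp by 1.81, S100a6 by 1.34 and Ms4a4a by 1.01 on the log2 scale. Ddit4 averaged 543 and 131 CPM (log2 change -2.18, adjusted p = 2.89e-05), and L1cam, Ly6i, Fam46a and Aldh3b1 changed by -1.42, -1.42, -1.34 and -1.26. The call was lost under 8 of 20 alternatives for Aldh3b1, 5 of 20 for L1cam and 4 of 21 for Ms4a4a. Chil3 is a marker of classical monocytes, and in sham mice it rests on 4 UMIs here. The 2 classical monocyte markers measured in the class had a median log2 change of 2.59. Chil3 is 1 of these 2 and the only one past the threshold, so that median largely repeats the Chil3 result. The class's own 7 markers had a median of -0.10, with 1 of them past the threshold and lower. Chil3 also averaged 0.685 and 11.8 CPM in B-like cells and 0 and 8.71 CPM in NK-like cells. Of the 37 genes, 33 had no overlap between the groups' mice, against 7.99% of genes tested and 2.86% by chance. The 37 were called on these same values, so this is not separate support either. With each library clustered on its own, no cluster of the DOCA-salt library was named nonclassical monocyte-like, so this result has no value there.

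In classical monocyte-like cells 1 of 1447 genes passed. Chil3 rose from 217 to 3631 CPM (log2 change 3.99, SE 0.39, adjusted p = 8.1e-05). The class has 16 sham cells, only 1 of them from sham mouse 3, and 113 DOCA-salt cells. Chil3 is one of the markers by which the class was named.

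B-like cells of DOCA-salt mice had less Otulin, which limits inflammatory signalling, less Zfp36l2, which shortens the life of messenger RNA, and less Glcci1, Strbp and Sesn1. Snrnp25, Imp4 and Pim1 rose, as did the myeloid transcripts Lyz2 and Apoe. In all, 162 of 8858 genes passed, 44 higher and 118 lower. The log2 changes were -1.06 for Otulin (113 and 53.5 CPM), -0.98 for Zfp36l2, -0.89 for Glcci1, -0.83 for Strbp and -0.79 for Sesn1. They were 0.81 for Snrnp25, 0.64 for Lyz2, 0.56 for Apoe and 0.51 for both Imp4 and Pim1. With clusters weighted equally 1 of 8858 genes passed and none of these named genes did, with Snrnp25 at 0.29 and Imp4 at 0.08. Over the alternatives that kept all mice, equal cluster weights included, the other named genes kept their direction. Otulin ran from -1.11 to -1.04, Zfp36l2 from -0.99 to -0.68 and Glcci1 from -0.95 to -0.80. Strbp ran from -0.996 to -0.651 and Sesn1 from -1.05 to -0.67. Lyz2 ran from 0.57 to 0.80, Apoe from 0.39 to 0.68 and Pim1 from 0.47 to 0.52. Over all alternatives Imp4 lost its call in 9 of 23 and Pim1 in 10 of 24. Of the lower genes 3 are haemoglobin genes, whose counts came mostly from 1 cell of sham mouse 2 with 20818 haemoglobin UMIs.

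NK-like cells had more Lgals3, Apoe and Lyz2, which myeloid cells express at high levels, and more Khdc1c and Lbr. Cdk2ap1, Tnfsfm13, Wapl, Taf10 and Bcl7c fell. In all, 59 of 6433 genes passed, 13 higher and 46 lower. Lgals3 averaged 27.0 and 75.7 CPM (log2 change 1.29, adjusted p = 0.00188), and Apoe, Khdc1c, Lyz2 and Lbr changed by 0.98, 0.97, 0.86 and 0.77. With each library clustered on its own Apoe changed by 0.36 and did not pass, and it lost its call under 7 of 23 alternatives in all. Cdk2ap1 averaged 177 and 88.4 CPM (log2 change -1.06, adjusted p = 4.2e-06), and Tnfsfm13, Wapl, Taf10 and Bcl7c changed by -0.98, -0.85, -0.79 and -0.78.

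T-like cells had more Tnfsf8, a ligand of activated T cells, and more of the growth and survival genes Myc, Bcl2 and Pim1. The MHC class II genes H2-Aa and H2-Eb1 fell, as did Tuba1a, Malat1 and Abhd17a. In all, 67 of 6010 genes passed, 27 higher and 40 lower. Tnfsf8 averaged 41.1 and 85.3 CPM (log2 change 1.03, adjusted p = 0.0026), and Myc, Bcl2 and Pim1 changed by 0.77, 0.74 and 0.66. H2-Aa averaged 301 and 131 CPM (log2 change -1.10, adjusted p = 2.8e-05), and H2-Eb1, Tuba1a, Malat1 and Abhd17a changed by -1.03, -0.97, -0.88 and -0.87. A C1q UMI, from a macrophage gene, was found in 44.9% of sham and 47.2% of DOCA-salt T-like cells. Without those cells H2-Aa changed by -0.56 and H2-Eb1 by -0.57, and neither passed. Myc and Pim1 each lost their calls under 10 of 25 alternatives, and the 27 higher calls fell to 3 with the stricter cell filter or a Leiden resolution of 0.5, 6 with a hashtag margin of 5 and 7 with doublets kept.

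**Figure D3:**
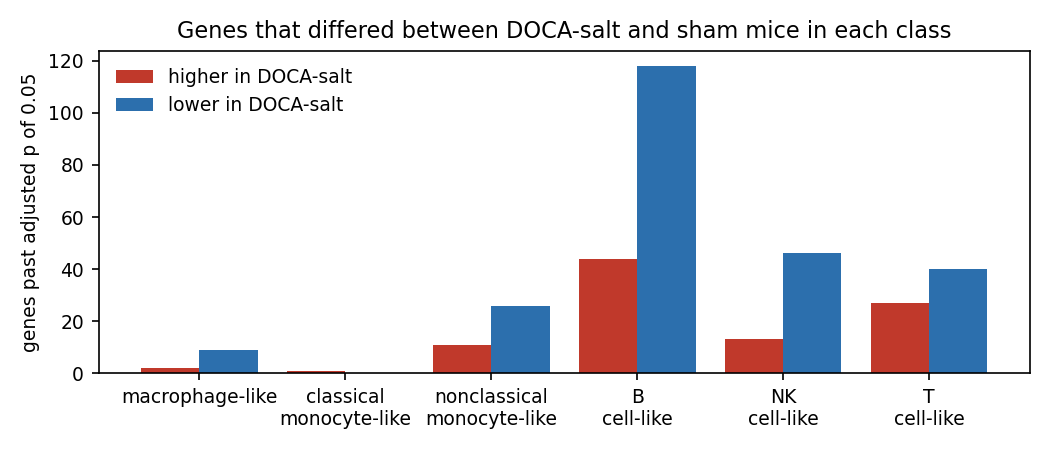
Number of genes past an adjusted p of 0.05 (edgeR) in each class, higher (red) and lower (blue) in DOCA-salt mice. In B-like cells 44 genes were higher and 118 lower, the largest counts of the 6 classes.

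Some lower genes were called in several lymphoid classes. B-like and NK-like cells shared 20 lower genes, B-like and T-like cells 17, and NK-like and T-like cells 18. The classes come from the same 8 mice and the same 2 libraries, so an effect of a mouse or a library would be shared too. In all 3 classes 14 genes fell, among them Malat1, Btg1, Jund, Klf13 and Gnai2, named after their values were seen, and 27 fell in at least 2 classes. Of 24 of these measured in macrophage-like cells 22 lay below 0, with 2 past the threshold. All 17 measured in nonclassical monocyte-like cells lay below 0, with 4 past the threshold. In at least 2 lymphoid classes 10 genes rose, among them Apoe, Lyz2 and Lgals3 in B-like and NK-like cells. In T-like cells these changed by -0.17, -0.02 and -0.14. The 1 gene called higher in all 3 classes was the mitochondrial gene mt-Atp8.

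**Figure D4:**
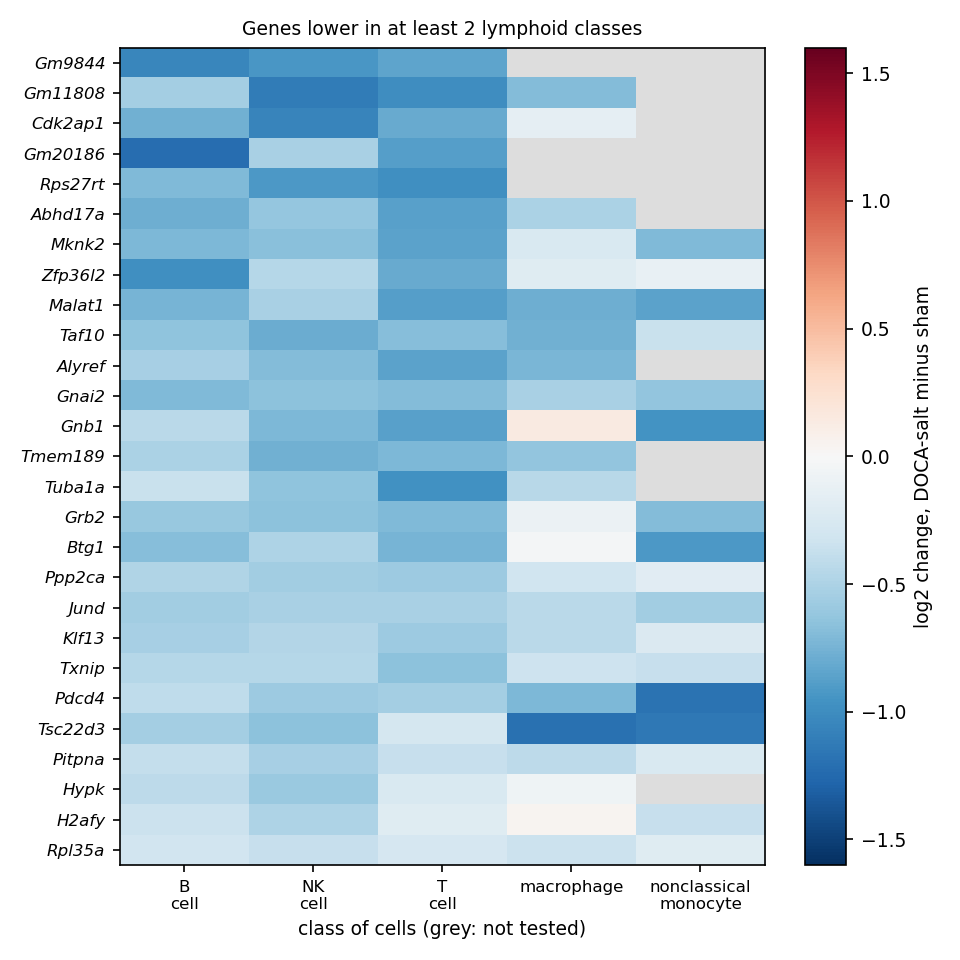
Log2 change (DOCA-salt minus sham) of the 27 genes lower in at least 2 of the B-like, NK-like and T-like classes, in these and in 2 myeloid classes; grey marks a gene that was not tested. Of 24 genes measured in macrophage-like cells 22 lie below 0.

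Over the 6 classes, camera called 21 lists at the preset correlation, and 2 of these hold with an estimated correlation. Both are in nonclassical monocyte-like cells. Matrix and fibrosis mediators, of which 3 of 19 were measured, rose (3 of 3 higher, median 0.63, estimated-correlation adjusted p = 0.0202), with Tgfbi, Lgals3 (0.63) and Tgfb1 (0.61) each past the threshold over all genes and 3 adjusted over the list alone. The 2 classical monocyte markers measured in this class, 1 of them Chil3, had a median of 2.59. Corticosteroid-responsive genes fell (5 of 5 lower, median -0.78, estimated-correlation adjusted p = 0.0202), with Ddit4, Tsc22d3 (-1.15) and Dusp1 (-0.78) past the threshold over all genes, Sgk1 at -0.56, and 3 adjusted over the list alone.

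The corticosteroid-responsive list also passed at the preset correlation, lower in DOCA-salt mice, in macrophage-like cells (median -0.70, estimated-correlation adjusted p = 0.214), B-like cells (-0.54, 0.113), NK-like cells (-0.42, 0.165) and T-like cells (-0.26, 0.0973). In macrophage-like cells all 9 measured members were lower, led by Per1, Tsc22d3, Fkbp5 (-1.05) and Dusp1 (-0.71), with 2 past the threshold over all genes and 2 adjusted over the list alone. In B-like cells Ddit4 (-1.01), Dusp1 (-0.60), Tsc22d3 (-0.54) and Nr3c1 (-0.27) led the list, with 1 past over all genes, Tsc22d3, and 4 adjusted over the list alone. In NK-like cells these were Ddit4 (-0.85), Sgk1 (-0.79), Tsc22d3 (-0.66) and Dusp1 (-0.42), with 2 past over all genes, Ddit4 and Tsc22d3, and 3 adjusted over the list alone. In T-like cells they were Dusp1 (-0.68), Ddit4 (-0.58), Tsc22d3 (-0.28) and Nr3c1 (-0.24), with 0 past over all genes by edgeR and 2 adjusted over the list alone.

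MHC class II genes were lower at the preset correlation in macrophage-like cells (median -0.53, estimated-correlation adjusted p = 0.233), classical monocyte-like cells (-1.22, 0.264) and T-like cells (-0.84, 0.0973), and higher in nonclassical monocyte-like cells (0.57, 0.393). In macrophage-like cells H2-Eb1, H2-Aa, Cd74 and H2-DMb1 changed by -0.71, -0.66, -0.63 and -0.55, with 0 past the threshold over all genes by edgeR and 6 of 9 members adjusted over the list alone. The 3 B cell markers measured in macrophage-like cells had a median of -0.47, with 0 past the threshold. In classical monocyte-like cells H2-DMb1 (-1.68), H2-Ab1 (-1.54), H2-Eb1 (-1.26) and H2-Aa (-1.22) led, with 0 past over all genes and 2 adjusted over the list alone. In T-like cells Cd74 (-0.85) and H2-Ab1 (-0.83) followed H2-Aa and H2-Eb1, and 4 members passed either way. In nonclassical monocyte-like cells H2-Aa (0.88), H2-Ab1 (0.71), H2-DMb1 (0.64) and H2-Eb1 (0.57) led, with 0 past either way. The difference between nonclassical monocyte-like and macrophage-like cells was 1.01 on the log2 scale (exact permutation p = 0.0571, adjusted p = 0.114 over 4 such differences), so the lists were not shown to differ between these classes.

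The other lists called at the preset correlation are given with the median log2 change and the estimated-correlation adjusted p. In macrophage-like cells NF-kB targets were lower (-0.28, 0.69), with Il1b (-1.40), Nfkbia (-0.68), Ccrl2 (0.38) and Cxcl2 (-0.36), and so were B cell activation genes (-0.68, 0.214), with Nr4a1 (-1.34), Cd83 (-0.78), Myc (-0.68) and Cd69 (0.55). No member of either passed over all genes, and 2 of each passed adjusted over the list alone. In classical monocyte-like cells matrix mediators were higher (0.10, 0.243), with Mmp8 (1.96), Fn1 (0.35), Lgals3 (0.10) and Tgfbi (0.04), and so were glycolysis genes (0.20, 0.373), with Tpi1 (0.75), Pkm (0.49), Hif1a (0.36) and Gapdh (0.20). Of these only 1 matrix gene passed adjusted over the list alone. In B-like cells TREM2 and lipid-associated genes were higher (0.31, 0.206), with Lgals3 (0.83) and Apoe past the threshold over all genes and Lgals1 (0.34) and Ctsd (0.27) short of it. Some markers of other cells were higher in B-like cells too, with a median of 0.94 for 4 classical monocyte markers, 2 of them past the threshold. The median was 0.93 for 2 neutrophil markers, with 0 past it. The 7 macrophage markers had a median of 0.18, also with 0 past it, and the medians for other cell types lay on both sides of 0.

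In NK-like cells NF-kB targets were lower (-0.48, 0.165), with Ccl4 (-0.72), Nfkbia (-0.48), Tnfaip3 (-0.48) and Ccl3 (-0.39), all 4 adjusted over the list alone and none over all genes. Cytotoxicity genes were lower (-0.25, 0.151), with Ccl5 (-0.49) past over all genes, Klrg1 (-0.44), Prf1 (-0.27) and Fasl (-0.25), and 5 adjusted over the list alone. T cell exhaustion genes were higher (0.41, 0.165), with Tigit (0.56), Cd160 (0.41) and Tox (0.03), 1 of them adjusted over the list alone. In T-like cells resident macrophage genes were lower (-0.87, 0.0973), with Cbr2 (-1.35) past over all genes, Pf4 (-0.87) and F13a1 (-0.18), and 2 adjusted over the list alone. Complement genes were lower (-0.81, 0.0973), with C1qa (-0.88), C1qc (-0.81) and C1qb (-0.60), all 3 adjusted over the list alone. B cell activation genes were higher (0.43, 0.258), with Myc past over all genes, Fas (0.43) and Cd69 (-0.07).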

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

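The tests here of reads shared between gene copies, the library, the corticosteroid response, B cell RNA, the single DOCA-salt mouse and the other groupings of mice were chosen only after the result was seen.

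In 5 of 152 groups of 4 mice tested, 1 mouse lay far from the other 3, where chance gives about 1 in 20. Sham mouse 1 had 0.722% neutrophil-like cells, against 0.158% to 0.253% in the other sham mice. Sham mouse 4 had 18.2% of its macrophage-like cells in the Mrc1-led cluster, against 27.1% to 27.8%. The same mouse had 136 CPM of Cyr61 in macrophage-like cells, against 69.9 to 76.5. DOCA-salt mouse 3 had 34.5 CPM of Bcl7c in NK-like cells, against 48.8 to 51.5. DOCA-salt mouse 1 had 1035 CPM of Spp1 in macrophage-like cells, against 14.9 to 29.6, and Spp1 was added to the groups tested because its values had been seen.

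Surface antibodies, which the comparisons above do not use, gave 96 comparisons of a class and a protein. In 16 the groups' mice did not overlap, and 0 passed adjustment by the exact permutation test, whose smallest unadjusted p of 0.0286 was reached by these 16 (adjusted p = 0.171). To pass, most of the 96 would have had to reach that smallest p. In most of these 16 the DOCA-salt mice were lower, as for CD39 in T-like cells (8.08% and 4.20% of antibody counts). CD39 was also lower without overlap in B-like (9.12% and 6.37%) and NK-like cells (7.96% and 6.28%). Its mean share was lower in every class compared, so this is not particular to T-like cells. In 3 of the 16 the DOCA-salt mice were higher. CD11b took 15.6% of antibody counts in sham and 21.1% in DOCA-salt macrophage-like cells, CD44 31.2% and 37.4% in B-like cells, and CD8a 15.1% and 24.2% in T-like cells. These are shares of a fixed total. As counts per cell the exact permutation p was 0.0286 for CD11b, 0.286 for CD44 (844 and 906) and 0.0571 for CD8a, so CD44 and CD8a are without overlap only as shares. The T-like cluster led by Igfbp4, Lef1 and Cd4 averaged 49.9% and 36.3% of its class. Another, led by Cd8b1 and Cd8a, averaged 29.8% and 39.9%. The CD8a value of the class also depends on this mix, which was not separated from CD8a per cell.

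Trem2 was higher in macrophage-like cells of DOCA-salt mice, with a log2 change of 0.71. Sequencing depth does not account for it among cells with at least 1000 UMIs, since with each of these thinned to 1000 UMIs the change was 0.85 (SE 0.29). Cells with fewer, 47 of 304 in sham and 52 of 742 in DOCA-salt mice, were left out of that test. A different mix of macrophage-like clusters does not either, since with the clusters weighted equally it was 0.96 (SE 0.28). Whether 1 mouse carries much of it stays open. Without DOCA-salt mouse 1 it was 0.52 (SE 0.20), which lies within 1 SE of the bound set for that explanation. The library also stays open, and the DOCA-salt treatment is a candidate explanation that these data cannot separate from it.

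MHC class II genes were lower in T-like cells. Less free B cell RNA is argued against, since the 3 B cell markers measured in T-like cells had a median log2 change of -0.0595, against -0.84 for the MHC class II genes. RNA of macrophages in T-like cells may contribute, and its possible sources are free RNA and cells stuck together. Without the T-like cells that hold a C1q UMI, the median was -0.31 (SE 0.20). This value lies on the side of the bound that was set for macrophage RNA. It is within 1 SE of that bound, so this test leaves macrophage RNA open. The 5 macrophage markers measured in T-like cells had a median of -0.81, close to the -0.84 of the MHC class II genes, with 0 past the threshold. C1qa averaged 112 and 55.5 CPM there (exact permutation p = 0.0571), while the share of T-like cells with a C1q UMI was 44.9% and 47.2%. The cells were sorted as single cells, which would remove most pairs but not free RNA. In the other lymphoid classes the macrophage markers had medians above 0, at 0.18 (7 markers, B-like) and 0.25 (3 markers, NK-like). C1qa averaged 69.9 CPM ± 13.7 and 79.4 CPM ± 13.1 in B-like cells (SD). In NK-like cells it averaged 62.6 CPM ± 26.5 and 84.9 CPM ± 28.3. For these genes this argues against less free macrophage RNA, which would lower them in every class of the library. It does not bear on cells stuck together.

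The genes lower in at least 2 of the B-like, NK-like and T-like classes are mostly not ribosomal protein genes or numbered gene models, whose reads are split between near-identical copies. These made up 18.5% of the 27, which argues against shared reads as the whole cause. A difference between the 2 libraries cannot be told apart from the treatment. Of the 24 genes measured in macrophage-like cells 91.7% were also below 0 there, but only 2 passed the threshold. The classes share mice and libraries, so this agreement in sign is not independent of the lymphoid calls. A weaker corticosteroid response is a candidate biological explanation. The median of the corticosteroid-responsive list was below 0 in 5 of 5 classes that measure it, but a shift of the whole library would give that too.

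All 35 splits of the 8 mice into 4 and 4 were refitted. For gene counts, the splits argue against a grouping by chance in 4 classes without excluding it. There 1 of 35 splits, the real one, gave as many, the smallest share this test can give. That share was not adjusted over the classes, which come from the same 8 mice. The real and the highest other counts were 37 and 5 in nonclassical monocyte-like cells, 162 and 1 in B-like cells, 59 and 17 in NK-like cells, and 67 and 5 in T-like cells. In macrophage-like cells the real split also gave the most, in 1 of 35 splits, but with 11 genes against 8 in the highest other, and the real count was 3 to 6 without some single mice, so chance is left open there. Chance is left open in classical monocyte-like cells too, where 7 splits gave at least 1 gene and the highest other gave 3. For numbers of lists at the preset correlation it cannot be excluded in any class. Splits with as many lists numbered 28 in macrophage-like cells (real 4, highest other 10), 9 in classical monocyte-like cells (3 and 4), 11 in nonclassical monocyte-like cells (3 and 4), 11 in B-like cells (2 and 4), 10 in NK-like cells (4 and 6) and 11 in T-like cells (5 and 8). The real split also parts the libraries, so these counts do not separate treatment from library.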

How the results depend on the processing

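The alternatives chosen after seeing the data were single macrophage-like clusters, T-like cells without a C1q UMI, shares without B-like cells, the unnamed B-led cluster counted as B-like, and leaving out mice within macrophage-like clusters. For B-like, NK-like and T-like cells they were also leaving out mice, the hashtag margin of 5, DESeq2 and no filter on low counts, for Trem2 and Tyrobp DESeq2 and no filter, and for the lists no filter. Where a cause is not named, the cause was not tested.

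The count of genes in macrophage-like cells, 11, moved by over 1.5 times under 17 of 27 alternatives. It was 151 with no filter on low counts, 31 with each library clustered on its own, 20 with DESeq2, 6 with the stricter cell filter, 4 thinned, 4 with cells weighted equally and 1 with a floor of 100 CPM. The 31 and the 151 include all 11 genes. Single clusters, with fewer cells, gave 0 (the C1q-led cluster), 0 (the Fabp5-led one, with 37 at an unadjusted p under 0.05) and 21 (the Mrc1-led one). Leaving out 1 mouse gave 3 to 23 genes, with 23, 4 and 22 without DOCA-salt mouse 1, 2 or 3. It gave 6, 6, 4 and 3 without sham mouse 1, 2, 3 or 4. Malat1 reversed, to 1.20 in the Fabp5-led cluster, the only reversal among the named genes past the threshold.

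In classical monocyte-like cells 1 gene became 22 with no filter, 163 with each library clustered on its own, 4 with doublets kept, 2 thinned, 2 with DESeq2 and 0 with cells weighted equally (limma, with 66 at an unadjusted p under 0.05), and 1 to 2 without 1 mouse, with 2 without any one of the 4 sham mice. In nonclassical monocyte-like cells 37 became 7 thinned and 18 with cells weighted equally, and 25 to 42 without 1 mouse. In B-like cells 162 became 293 with no filter, 96 with a floor of 100 CPM, 55 thinned, 101 with DESeq2, 1 with clusters weighted equally, where a cluster of 24 cells weighs as much as the largest, and 82 to 173 without 1 mouse. It was 85, 98 and 94 without sham mouse 2, 3 or 4, and 100, 82 and 94 without DOCA-salt mouse 1, 2 or 4. In NK-like cells 59 became 120 with no filter, 38 with a floor of 100 CPM, 39 with a hashtag margin of 5, 12 thinned and 24 with cells weighted equally, and 33 (without sham mouse 4) to 65 without 1 mouse. In T-like cells 67 became 159 with no filter, 24 with the stricter cell filter, 41 with doublets kept, 22 at a Leiden resolution of 0.5, 31 with a hashtag margin of 5, 18 thinned, 24 without cells that hold a C1q UMI and 42 with clusters weighted equally, and 36 to 111 without 1 mouse, with 36, 38 and 41 without sham mouse 2, 3 or 4 and 111 without DOCA-salt mouse 1. Thinning and floors test fewer genes. Scaling by library totals changed the share of higher calls from 22.0% to 35.1% in NK-like cells and from 40.3% to 28.8% in T-like cells.

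Trem2 stayed higher under all 26 alternatives. It passed only with no filter on low counts (0.79, adjusted p = 0.0167 by edgeR), chosen after the data were seen. There the class's median log2 change was 0.125, against -0.0002 with the filter, and 99 genes were higher and 52 lower. The share of cells with a UMI was 20.5 percentage points higher (exact permutation p = 0.0286, not adjusted and not corrected for depth). Trem2's adjusted p reached 0.517, and its log2 change ran from 0.52 to 0.84 without 1 mouse. Tyrobp reversed to 0.49 in the Mrc1-led cluster, the macrophage-like cluster with the lowest median of UMIs, and ran from -0.15 to -0.05 without 1 mouse.

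Lists past the threshold, 21, became 35 with no filter, 13 thinned and 9 with clusters weighted equally, which has fewer classes, and 20 to 27 without 1 mouse. No share passed under any alternative with all mice, where the smallest exact permutation p of 0.0286 makes a pass after adjustment hard to reach. Without 1 mouse none could, since the smallest exact permutation p is then 0.0571. With B-like cells left out of the denominator the T-like share reversed to -0.25 percentage points. The Fabp5-led cluster's share of macrophage-like cells ran from -5.89 to 2.50 percentage points without 1 mouse, and reversed to 0.19 without sham mouse 1, 2.18 without DOCA-salt mouse 3 and 2.50 without DOCA-salt mouse 4.

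Over 51 named results and 1184 alternatives, 995 kept their direction and side of the threshold, 188 kept the direction only and 1 reversed. Weighting clusters equally could not be run for classes of 1 cluster, and nonclassical monocyte-like cells had no gene expression value with each library clustered on its own.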

Other observations

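Haemoglobin RNA, looked at after the data were seen, differed between the libraries. A haemoglobin UMI was found in 12.3% ± 0.631 of cells of sham mice and 1.11% ± 0.201 of cells of DOCA-salt mice (SD, n = 4; exact permutation p = 0.0286, the smallest it can give), in all classes together. One cell of sham mouse 2, assigned to a B-like cluster, held 20818 haemoglobin UMIs, 87.8% of its UMIs, and the next highest cell held 50. The free RNA of the 2 libraries therefore differs, and no test separates perfusion, sample handling and treatment as its origin.

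Xist was at 0 CPM and Ddx3y was detected in macrophage-like cells of all 8 mice, with a mean of 44.2 CPM in sham and 44.5 CPM in DOCA-salt mice.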
